A study of Mus musculus with 3 samples.

How the data were processed

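Gene expression was measured in 3 samples of mouse peritoneal macrophages, 1 array per group. Per the labels' protocols, mice received an intraperitoneal injection of 3 ml of 4% thioglycolate, an irritant that recruits macrophages, and cells were collected by lavage after 3 days. The cells were cultured for 2 h and then infected with Listeria monocytogenes, a bacterium that replicates inside macrophages, at a multiplicity of infection of 0.2 for 6 h in medium without antibiotics. The groups were uninfected wild type, infected wild type and infected MyD88-/-, the last lacking by its label the adaptor protein of most Toll-like receptors and of interleukin-1 family receptors. The labels do not say how long the uninfected cells stayed in culture, how many mice each sample came from or which sex they were. No uninfected MyD88-/- sample was analysed here.

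RNA input was 20 ng of total RNA per sample, amplified to cDNA with a whole-transcriptome kit, and 5 ug of cDNA was fragmented and labelled with biotin, per the labels' protocols. The deposited values are single-colour Affymetrix intensities, 1 linear MAS5 signal per probe set, and MAS5 is named per the submitters' processing notes without a version. Every array's mean signal after trimming 2% at each end was 500, the mark of a scaling of each array to that target by the authors. No detection calls were used here. MAS5 subtracts each probe's mismatch estimate, so weak signals scatter widely on a log scale and a floor was needed.

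The 45101 probe sets were named through the platform annotation provided for this series. Of these, 34958 carried 1 gene symbol, 932 carried several and 9211 had no symbol listed. Only the first kind was used for genes. Entrez identifiers were matched to a RefSeq gene table of assembly GRCm38.p6, which found 34754 of them, or 99.4%, and changed 0 symbols. Coordinates of that table were not used beyond chromosome names and gene order. A gene was represented by its probe set of highest mean log2 signal, which gave 18194 genes. Several interferon-induced and sterol genes, such as members of the fixed lists whose probe sets carry no single symbol here, were therefore unnamed, and list sizes below are those of measured members.

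The background floor was the 95th percentile of the signals of 81 probe sets of olfactory, vomeronasal and trace amine receptors, which macrophages are not known to express. It was 59.2, 44.9 and 66.5 on the uninfected, infected wild-type and infected MyD88-/- arrays, and their geometric mean of 56.1 was used for all. Signals below the floor were raised to it. A fold with its lower side at the floor is written as at least that fold, and no fold was formed where both sides were at or below it.

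With 1 array per group no test of a difference between groups was possible, so no p-values, standard deviations between replicates or counts of significant genes are given. Genes were counted as higher or lower by size, at 2-fold or more. For 35 gene lists the median log2 difference was set among 10000 random lists of the same size whose members were drawn from the same of 20 bins of mean signal, as a description of these arrays. Because the median gene itself differed between arrays, list medians are given relative to the median of all measured genes. Infection genes were chosen on the mean of both infected arrays minus the uninfected array and then split by the difference between the infected arrays. Lists, thresholds, the floor and most alternatives were fixed before the data were examined, as was the rule for named genes. That rule took Myd88, Tnf, Il1b, Il6, Il12b, Nos2, Ifnb1, Cxcl10 and Ifit1 always, up to 4 members of largest difference from each list described, and the 10 largest differences in each direction among genes whose brighter array was at least 4 times the floor, from the top down. A gene named in a comparison could be given in the others. Xist, the Y-linked genes other than Eif2s3y, the X-linked partners of Y-linked genes, Bcl2l12, Ly6e, Ifi27l2a, Klrd1, Cd3d, Prf1, Cd247 and the amino acid response genes were chosen after their values or those of related genes were seen.

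The only measure of error within these data is the disagreement between probe sets of the same gene. Across 5292 genes with more than 1 probe set above the floor, the log2 differences of the 2 brightest probe sets were compared. Their standard deviation was divided by the square root of 2, to stand for 1 probe set. It was 0.40 for infected against uninfected wild type, 0.33 for infected MyD88-/- against infected wild type and 0.31 for infected MyD88-/- against uninfected wild type. Among the 1225 of them with a brighter probe set that differed by at least 2-fold with infection in wild type, 96.1% had another probe set of the same sign. Genes whose brightest probe set passed 2-fold in a comparison described while another probe set did not include Inhba, Sesn1, Tpsb2, Tlr3 and Ddit3. These figures leave out variation between animals, cultures and hybridizations, and the number of arrays limits the precision of every value.

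The calling was tested on simulated data for infected against uninfected wild type, with 200 changed genes among 18194 and noise set from the disagreement between probe sets. The noise was 0.18 per array, from an outlier-resistant spread of 0.26 for infected MyD88-/- against infected wild type. The calling recovered 100% of the genes changed 4-fold and 100% of those changed 8-fold, and it called 1 of 11942 unchanged genes. That noise is small beside a 2-fold threshold, so this checks the code and not the error rate of these arrays. For infected MyD88-/- against uninfected wild type, 8 of 200 random lists of 20 unchanged genes, 4%, fell outside the central 95% of matched lists. A small share is built in here, because the simulated noise was independent between genes. This too checks the code, and does not cover lists whose genes vary together.

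Alternatives were quantile normalization, equal medians of expressed genes, other floors or a constant of 16 added before taking logs, the mean of a gene's probe sets, leaving out probe sets of less specific design, thresholds of 4-fold and 1.5-fold, and other choices of the infection genes. Scaling to bacterial and phage hybridization controls and leaving out genes on the X and Y chromosomes were chosen after seeing the data. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.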

Results

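Transcript levels were measured on whole-genome mouse arrays in thioglycolate-elicited peritoneal macrophages from 3 groups with 1 array each: uninfected wild type, wild type infected with Listeria monocytogenes for 6 h, and infected MyD88-/-. No group had a replicate, so no difference below has a replicate check, and genes are called higher or lower by size alone. Of 18194 genes, 12151 were above the background floor on the uninfected array, 11366 on the infected wild-type array and 11725 on the infected MyD88-/- array, and 10585 were above it on all 3. The 3'/5' signal ratio of the beta-actin control probe sets was 0.980, 1.01 and 0.991 in that order, and that of Gapdh was 1.41, 1.53 and 1.45. Housekeeping reference genes had a median log2 difference of -0.07 between infected and uninfected wild type, with 0 of 11 members 2-fold apart, and ribosomal protein genes one of 0.13, with 0 of 22 apart. Relative to the median of all genes these were 0.20 and 0.40.

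Myd88, the gene named by the knockout label, was measured by 1 probe set. Its signal was 498 in uninfected wild type, 1399 in infected wild type and 483 in the array labelled MyD88-/-. The labels do not say which part of the gene was deleted, and a probe set outside that part detects the remaining transcript, so this signal does not check the genotype.

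The comparison of infected with uninfected wild-type macrophages asks what Listeria infection does to macrophages with an intact receptor pathway. Cytokine genes showed the largest difference of any list. All 23 measured members of the proinflammatory cytokine and mediator list were at least 2-fold higher after infection, with a median log2 difference 4.99 above that of all genes, above 10000 of 10000 matched random lists. Tnf, a central inflammatory cytokine, had a signal of 338 on the uninfected and 14387 on the infected array, which is 42.6-fold, and Il1b was 39.4-fold higher. Il6 was at least 95.5-fold higher, Il1a 100-fold, and Il12a and Il12b, which encode the subunits of interleukin-12, at least 66.5-fold and at least 34.8-fold. Il1f9, an interleukin-1 family cytokine, had the largest fold of genes above the floor on both arrays, from 63 to 10612 or 168-fold.

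Chemokine genes were higher in 13 of 22 measured members and lower in 1, with a median 2.76 above all genes. Cxcl10, which attracts activated T cells, was 163-fold higher, Cxcl3 114-fold, Ccl4 44.2-fold and Cxcl2 18.1-fold. Of 24 NF-kB pathway and feedback genes 19 were higher and 0 lower, among them Nfkbiz at 14.2-fold, Zc3h12a at 12.5-fold, Traf1 at 14.8-fold and Tnfaip3, an inhibitor of the pathway, at 5.57-fold. Both list medians exceeded 10000 of 10000 random lists. Edn1, the gene of the vasoconstrictor endothelin, was at least 84.0-fold higher, and Mir155hg, the host gene of an inflammatory microRNA, was 54.2-fold higher. Acod1, the enzyme that makes itaconate, and Lcn2, which binds bacterial siderophores, were 31.5-fold and 30.2-fold higher, while Nos2 stayed weak, below the floor in uninfected cells and at a signal of 135 after infection.

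The interferon program was also present. Ifnb1, the interferon beta gene, had signals of 5.39 on the uninfected and 1048 on the infected array, at least 18.7-fold higher. Of 41 interferon-stimulated genes 40 were at least 2-fold higher, with a median 2.58 above all genes, and so were 9 of 9 interferon-inducible GTPases, with a median 3.95 above all genes. Ifit1 was 42.8-fold higher, Cmpk2 52.5-fold, Ifit2 37.6-fold, Mx1 30.0-fold, Gbp3 18.7-fold and Gbp2 18.4-fold. Ifng, which natural killer and T cells make in quantity, was at 3.29 on the uninfected and 1048 on the infected array. MHC class I presentation genes lay 1.06 above all genes with 2 of 12 members past 2-fold, and their regulator Nlrc5 was 5.43-fold higher.

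Genes of the oxidative stress response controlled by NRF2 lay 1.51 above all genes, with 8 of 15 higher, including the cystine transporter gene Slc7a11 at 31.6-fold, Nqo1 at 9.30-fold and Gclc at 7.58-fold. Immediate early and heat shock genes lay 1.73 above all genes, with 18 of 28 higher, including Maff at 14.8-fold, Ier3 at 9.75-fold, Hspa1a at 9.46-fold and Egr1 at 8.87-fold. All these list medians, from the interferon genes onward, exceeded at least 9998 of 10000 random lists.

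In the other direction, 14 of 18 cholesterol biosynthesis genes were lower after infection and 0 higher, with a median of -1.28 relative to all genes, below 10000 of 10000 random lists. Dhcr7, the enzyme of the last step to cholesterol, had 3134 on the uninfected and 217 on the infected array, 14.4-fold lower. Fdps and Lss were 6.10-fold and 5.86-fold lower. Cell cycle genes were lower in 19 of 33 members and higher in 1, among them Uhrf1 at 4.66-fold and Aurkb at no less than 5.61-fold. Of 25 macrophage identity genes 9 were lower and 0 higher, led by the monocyte chemokine receptor gene Ccr2, at least 27.6-fold lower, the nucleotide receptor gene P2ry6 at 12.8-fold and the apoptotic cell receptor gene Mertk at 4.68-fold. That list's median was -0.08 relative to all genes and 0.02 when probe sets of less specific design were left out. It lay below 9975 of 10000 random lists matched on signal, but at percentile 33.5 of unmatched ones. Arhgap19, Pgm2l1, Scd2, Sesn1 and Rassf2 were each lower by 15.0-fold to 24.7-fold. The adaptor gene of inflammasomes, Pycard, had signals of 3820 on the uninfected and 463 on the infected array, while Nlrp3 was 16.6-fold higher.

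Some markers of other cells differed as well. Of 8 mast cell and basophil genes 5 were higher in infected wild type, among them Hdc at 18.2-fold, Tpsb2 at least 5.13-fold and Mcpt4 at least 4.31-fold. Tpsb2 and Mcpt4 stayed weak, at 288 and 242 after infection. Of 12 neutrophil genes 6 were higher, including S100a9 at 19.2-fold and S100a8 at 4.57-fold, and of 13 B cell genes 5 were higher, including Ms4a1 at 5.52-fold, and 1 was lower, Cd22 at 4.35-fold. Among natural killer cell genes other than Ifng, Gzmb had a signal of 108 and Klrk1 one of 145 on the infected array. Prf1 had 718 on the uninfected and 575 on the infected array. Fibroblast and mesothelial genes were lower in 4 of 13 members and higher in 1, with Col1a1 at 3917 on the uninfected and 645 on the infected array. Their median was at percentile 24.7 of matched random lists, however. That of T cell genes was at 91.0 and that of dendritic cell genes at 62.7, all inside the central 95%. The medians of mast cell, neutrophil and B cell genes were above 10000 of 10000 random lists. That of the 6 measured natural killer cell genes, Ifng included, was above 9999.

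The sex-linked genes also differed between these arrays. Xist, the RNA of the inactive X chromosome of females, had a signal of 8688 on the uninfected array against 23 and 41 on the infected wild-type and MyD88-/- arrays, with all 3 of its probe sets alike. The Y-linked Eif2s3y had signals of 17.0, 2881 and 2510, and all 9 probe sets of Eif2s3y, Kdm5d and Uty were at or below the floor on the uninfected array while 8 of 9 were above it on each infected array. The uninfected array thus carried a female pattern and both infected arrays a male pattern, a difference that every comparison with the uninfected array crosses. Leaving out genes on the X and Y chromosomes, an alternative added after seeing this, gave 924 higher and 2319 lower genes in wild type in place of 945 and 2378. It kept 12306 of 12679 measured genes, so these counts could change little. Genes of other chromosomes that may differ by sex stayed in, so it does not check for an effect of sex.

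**Figure D1:**
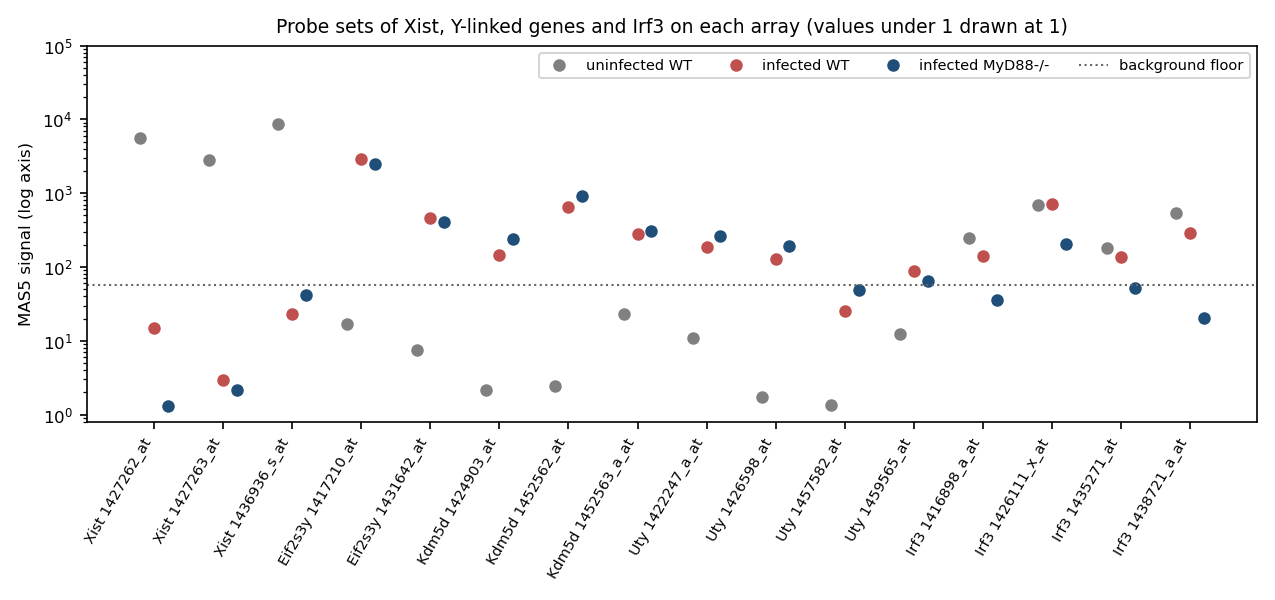
Signal (log axis) of every probe set of Xist, of the Y-linked genes Eif2s3y, Kdm5d and Uty, and of Irf3 on the 3 arrays; each dot is 1 array and the dotted line the background floor of 56.1. Xist was bright only on the uninfected array, 8 of 9 probe sets of Y-linked genes exceeded the floor only on the infected arrays, and Irf3 was lower on the array labelled MyD88-/- on all 4 of its probe sets.

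Counted over all 12679 measured genes, 945 were at least 2-fold higher and 2378 at least 2-fold lower after infection of wild type, and 314 and 369 passed 4-fold. Higher calls were 28.4% of all calls with the deposited scaling, 45.9% after quantile normalization (1247 higher, 1471 lower) and 53.0% with equal medians of expressed genes (1508 and 1338). The median log2 difference of all genes was -0.27 as deposited, which is why list medians are given relative to all genes.

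The comparison of infected MyD88-/- with infected wild type asks which part of the response depends on the adaptor, if the label is right. No uninfected MyD88-/- array was analysed, so a difference can also be one between uninfected cells of the 2 genotypes. Genes induced by interferon differed most. All 41 measured interferon-stimulated genes were at least 2-fold lower on the array labelled MyD88-/-, with a median of -3.21 relative to all genes, and the 9 measured interferon-inducible GTPases were all lower, with a median of -4.03. Oasl1, a member of the antiviral oligoadenylate synthetase family, had the largest fold of genes above the floor on both arrays, from 9540 to 118 or 81.1-fold, followed among interferon-stimulated genes by Cmpk2 at 41.0-fold, Ifit3 at 36.4-fold and Slfn1 at 28.5-fold. Ifi47 was 29.4-fold lower and Gbp3 17.6-fold. Ifnb1 was at 16, below the floor, so that it was at least 18.7-fold lower, and Ifng at 2.84.

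Of 23 cytokine and mediator genes 19 were lower on the MyD88-/- array and 0 higher, with a median of -2.31 relative to all genes. Edn1 was 59.6-fold lower, Il6 36.3-fold, Csf3, the granulocyte growth factor gene, at least 32.7-fold, and Il12b had 122 against 1953. Il1b was 7.74-fold and Tnf 3.78-fold lower. Of 22 chemokine genes 11 were lower, with Cxcl10 at 45.5-fold, Ccl5 at 25.4-fold, Cxcl5 at 17.2-fold and Ccl7 at 15.4-fold. Cxcl2 and Cxcl3, which attract neutrophils, kept signals of 16961 and 8978 against 24350 and 16439 in infected wild type. NF-kB pathway genes were lower in 8 of 24 members, including Zc3h12a at 6.97-fold and Nfkbiz at 5.60-fold. Each of these list medians, and those of the interferon groups, lay below 10000 of 10000 matched random lists.

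MHC class I presentation genes were lower in 5 of 12 members, with Nlrc5 at 5.46-fold and Psmb9 at 2.74-fold, and their median was -0.88 relative to all genes. Pattern recognition receptors and adaptors were lower in 6 of 24 members and higher in 1, among the lower ones them Cgas, the cytosolic DNA sensor, at 5.53-fold and the endosomal receptor gene Tlr3 at 3.79-fold. Irf3, the transcription factor gene that acts upstream of Ifnb1, had a signal of 206 against 711 in infected and 692 in uninfected wild type. That is 3.45-fold lower than infected wild type. Its other 3 probe sets were below the floor on the MyD88-/- array, so that their differences are bounds, from at least 2.44-fold to at least 5.16-fold. Among 4318 genes with at least 3 probe sets, Irf3 was the 1 gene for which every probe set was at least 2-fold lower on the MyD88-/- array than on both wild-type arrays, a search made after its value was seen. Signals were raised to the floor, so genes with a probe set below 2 times the floor on a wild-type array could not pass. How many of the 4318 could pass was not counted. Mast cell genes were lower in 5 of 9 members and higher in 1, and neutrophil genes lower in 5 of 12 and higher in 0. Hdc was 12.8-fold, Stfa2l1 10.8-fold and S100a8 7.17-fold lower. Natural killer cell genes, Ifng included, were lower in 2 of 5 members and higher in 0. Their median was -1.08 relative to all genes, at percentile 0.135 of matched random lists. For 4 of these 5 the MyD88-/- side was at the floor, while Prf1 had 734 against 575. Of 3 eosinophil genes 1 was lower and 0 higher, with a median of -1.07 relative to all genes, at percentile 1.04. Whether the infected arrays differed in their share of these cells was not tested.

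Heat shock and immediate early genes were lower in 7 of 28 members and higher in 0, with a median of -0.58 relative to all genes, below 10000 of 10000 random lists. Hspa1b and Hspa1a, which encode inducible chaperones, were 5.83-fold and 4.16-fold lower, Egr1 3.89-fold and Ier3 3.19-fold. Antimicrobial effectors were lower in 5 of 19 members and B cell genes lower in 3 of 13 and higher in 1 (Cd22), with medians of -0.44 and -0.60 relative to all genes. Inflammasome genes were lower in 4 of 12 members and higher in 2, and apoptosis genes lower in 1 of 16 and higher in 1, with medians of -0.44 and -0.46. These medians lay below at least 9971 of 10000 random lists.

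Some lists held no gene 2-fold apart between the infected arrays. None of the 15 NRF2 genes, 15 glycolysis genes, 30 oxidative phosphorylation genes or 19 unfolded protein response genes differed by 2-fold. Of the genes higher on the MyD88-/- array, 552 were lower in infected than uninfected wild type, where independent lists would share 130 and 20 simulated sets of unchanged arrays 0. The simulated noise, taken from probe set disagreement, is too small to give 2-fold calls, so that 0 measures nothing of the sharing. The differences of infection and of MyD88-/- correlated at -0.742, against -0.500 in simulated unchanged arrays that share the infected wild-type array. Part of the excess may come from that sharing. A response of the infected wild-type array that depends on signal may also add to the 552. For 1562 genes with probe sets at least 4-fold apart in signal, the median gap in log2 difference, dimmer minus brighter, was -0.24 with infection. In MyD88-/- against infected wild type that gap was 0.16. The 552 was counted under the deposited scaling, where 697 genes were higher on the MyD88-/- array. Quantile normalization gave 382 such higher genes and equal medians 363. Among higher genes above the floor on both arrays Arhgap19 had the largest fold, 7.69-fold, with signals of 1800, 73 and 560 in uninfected wild type, infected wild type and infected MyD88-/-. St6gal1, a sialyltransferase gene, had 2661, 385 and 2397, Ypel2 2382, 370 and 2246, and Zdhhc14 875, 58 and 315. Nrep and Adgrd1, next in order, were above the uninfected level on the MyD88-/- array, with 270, 109 and 580 and with 196, 148 and 779. Alternative activation genes went both ways, with 2 of 18 higher, such as Retnla at 4.86-fold, and 3 lower, such as Cish at 5.19-fold, and their median was at percentile 48.6. Both infected arrays carried the male pattern of Xist and Y-linked genes, so this comparison does not cross sexes.

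Over 12287 measured genes, 697 were at least 2-fold higher and 555 lower on the MyD88-/- array, and at 4-fold 25 were higher and 166 lower. Higher calls were 55.7% of all 2-fold calls as deposited, 36.9% after quantile normalization (382 higher, 653 lower) and 32.4% with equal medians (363 and 756), so the direction of the excess at 2-fold changed with the scaling. The median gene was 0.14 higher on the MyD88-/- array as deposited.

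**Figure D2:**
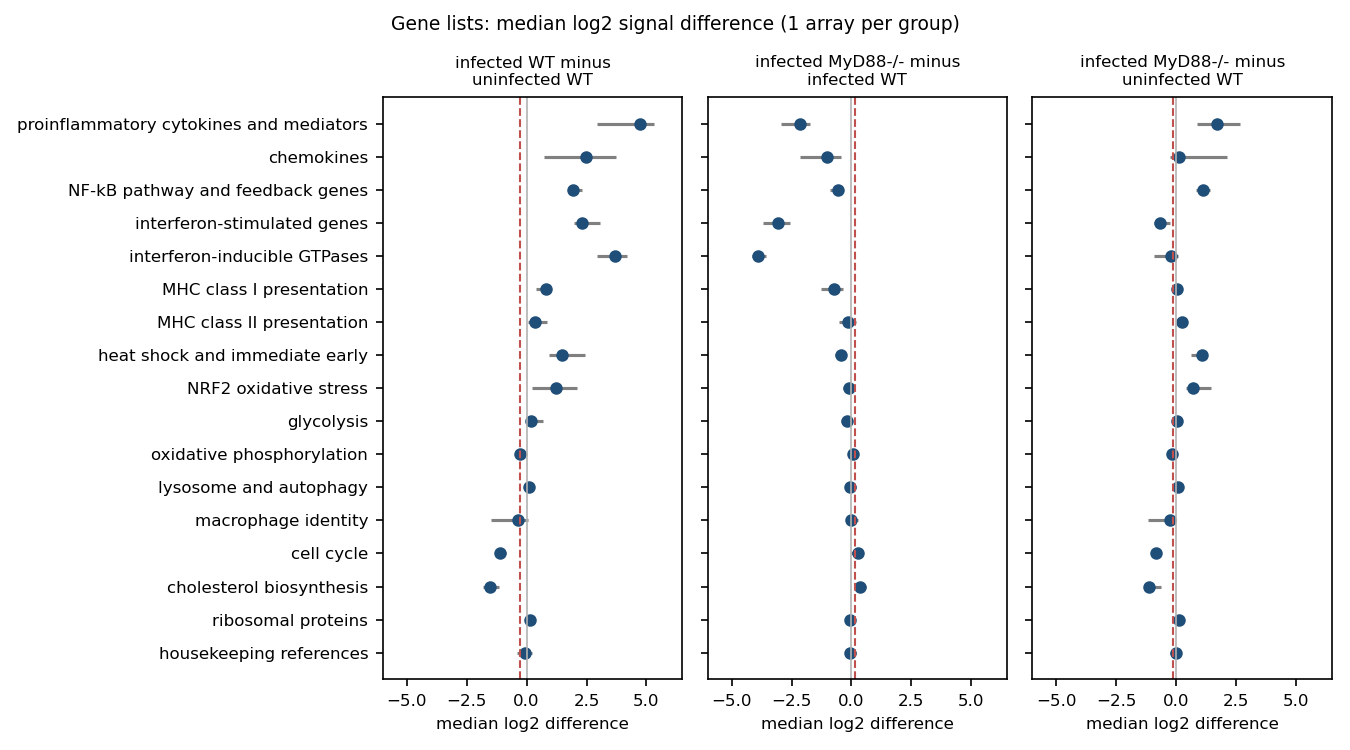
Median log2 signal difference of 17 gene lists in each of the 3 comparisons; dots are medians over measured members, grey lines the range of medians when members are resampled (95%), the red dashed line the median of all genes. Interferon-stimulated genes lay 2.58 above all genes in infected against uninfected wild type and -3.21 relative to all genes in infected MyD88-/- against infected wild type, while NRF2 genes differed from all genes by -0.26 in the latter.

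**Figure D3:**
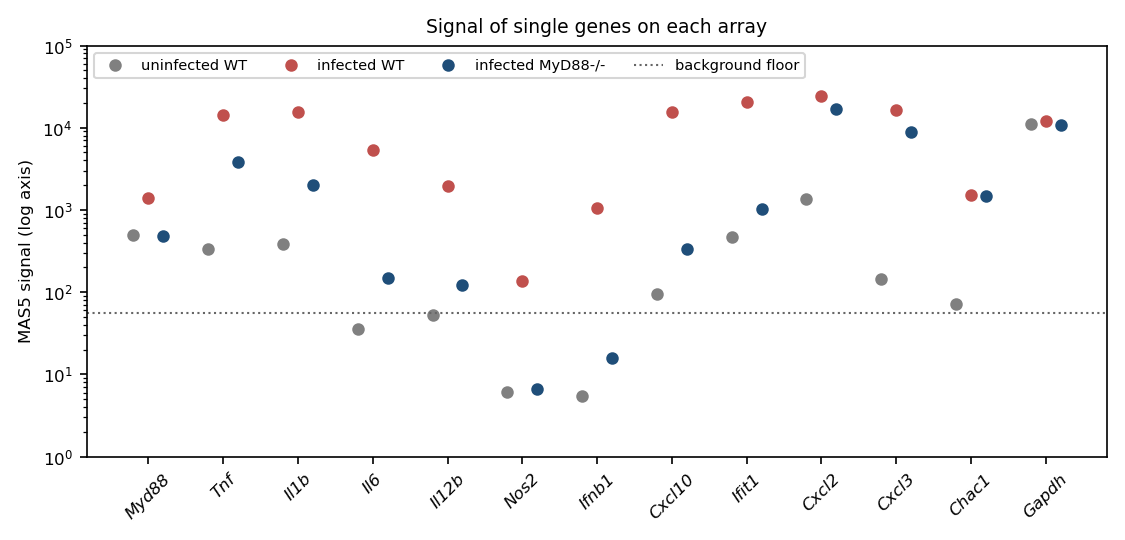
MAS5 signal (log axis) of single genes on each array, 1 dot per array, with the background floor of 56.1 as a dotted line. Tnf stood at 338, 14387 and 3804 and Ifnb1 at 5.39, 1048 and 16 on the uninfected, infected wild-type and infected MyD88-/- arrays.

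The infection response on the array labelled MyD88-/- was read against the shared uninfected wild-type array. Of 20 measured cytokine genes 13 were higher and 0 lower, with a median 1.82 above all genes. Il1a was 18.8-fold higher, Ptgs2, the inducible prostaglandin synthase, 13.7-fold, Inhba 12.3-fold (its other probe set had a log2 difference of 0.15) and Tnf 11.3-fold, whereas Il6 was at least 2.63-fold and Il12b at least 2.17-fold higher. Chemokines split, with 7 of 17 higher and 2 lower. Cxcl3 was 62.0-fold higher, the largest fold of genes above the floor on both arrays, Cxcl2 12.6-fold, Ccl4 11.2-fold and Ccl3 7.21-fold. NF-kB genes were higher in 13 of 24 members, and Relb and Nfkbie reached 1166 and 3538, above their signals of 850 and 2721 in infected wild type.

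The NRF2 genes were higher in 7 of 15 members, with Slc7a11 at 18.8-fold, Nqo1 at 7.24-fold and Gclc at 5.41-fold. Heat shock and immediate early genes were higher in 15 of 28 members, with Maff at 10.1-fold, although 7 members of the list were lower than in infected wild type. Gem was at least 34.2-fold higher, Chac1 20.9-fold and Serpinb2 19.2-fold. These lists and the cytokine and NF-kB lists exceeded 10000 of 10000 matched random lists. Cholesterol genes were lower in 11 of 18 members, with Dhcr7 at 4.28-fold and Fdps at 3.71-fold, and cell cycle genes in 12 of 33. Ccr2 was 21.1-fold, Fcgr1 9.86-fold and P2ry6 8.73-fold lower. Fibroblast and mesothelial genes were lower in 3 of 13 members, with Col1a1 at 4.94-fold and Wt1 at 2.85-fold, and of 3 eosinophil genes Siglecf was 8.37-fold lower and Il5ra 1.27-fold higher. The medians of these lists lay at percentiles 16.1 and 14.9 of random lists, inside the central 95%.

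The interferon-stimulated list as a whole lay below uninfected wild type on this array, though 27 of its 41 members were within 2-fold. Of 41 members 12 were at least 2-fold lower and 2 higher, with a median of -0.56 relative to all genes, below 10000 of 10000 random lists. Oas3 was 5.16-fold lower, Oasl2 3.77-fold and Oas2 at least 3.53-fold, while Irf1 was 3.38-fold and Ifit1 2.17-fold higher. The interferon-inducible GTPases did not lie lower as a list. Their median was -0.11 relative to all genes, at percentile 24.5 of random lists. Of 8 measured, 1 was higher, Gbp2 at 2.60-fold, and 1 lower, Irgm2 at 2.37-fold. The chemokine gene Cxcl10 was 3.58-fold higher. The difference of sex-linked genes between the arrays applies to this comparison and to each of these lists too.

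In all, 531 genes were higher and 1084 lower among 12654, with higher calls 32.9% of all calls as deposited, 48.0% after quantile normalization and 46.8% with equal medians. Genes at least 2-fold higher on both infected arrays than on the uninfected array numbered 409 and those lower on both 845, among 12370 measured in both. Independent lists of these sizes would share 37.7 and 208 genes, and 20 simulated sets of 3 unchanged arrays shared 0 and 0 on average, which their small noise makes near certain. The differences correlated at 0.753, against 0.504 in those simulated arrays. Part of the excess may come from the shared uninfected array, which was measured once.

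**Figure D4:**
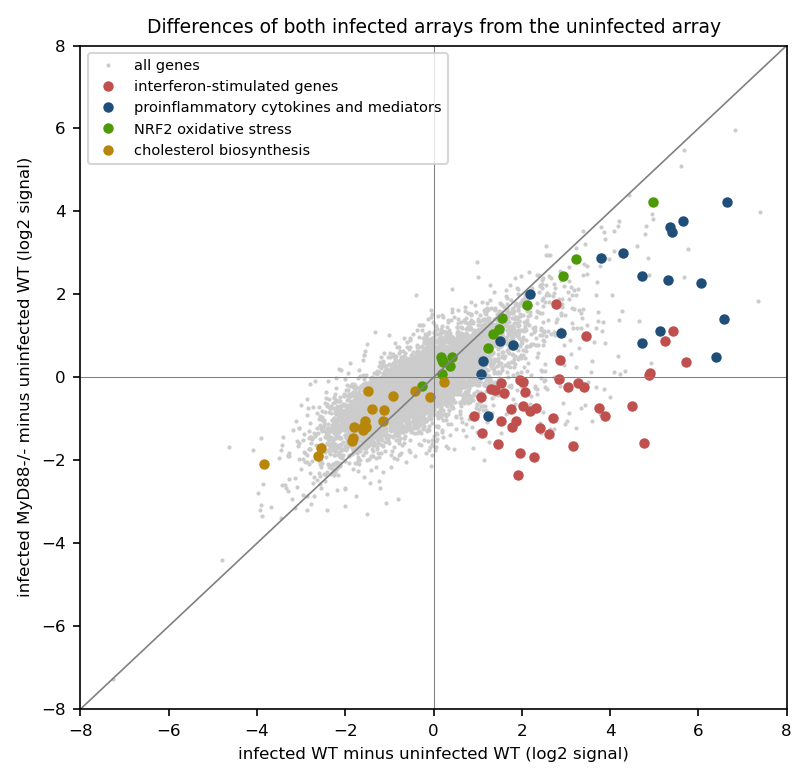
Log2 signal difference of infected MyD88-/- (vertical) and of infected wild type (horizontal) from the uninfected wild-type array; grey dots are genes, coloured dots members of 4 fixed lists, and the diagonal marks equal differences. Members of the interferon-stimulated list sit to the right with vertical values from -2.37 to 1.76, while NRF2 and cholesterol genes lie nearer the diagonal.

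Infection genes were finally split by their difference between the infected arrays. The cause of that difference is open, since the genotype is unchecked and no uninfected MyD88-/- array was analysed. Of 659 genes at least 2-fold higher on the mean of both infected arrays, 224 or 34.0% were at least 2-fold lower on the MyD88-/- array than in infected wild type, 5 were higher and 430 lay between. Among 1553 genes lower on that mean, 340 or 21.9% were at least 2-fold higher on the MyD88-/- array. That share was counted under the deposited scaling alone, where 697 of all measured genes were higher on that array. Quantile normalization gave 382 such genes and equal medians 363. When genes were chosen on infected wild type alone, 406 of 945 were lower on the array labelled MyD88-/- and 1 was higher. When chosen on infected MyD88-/- alone, 83 of 531 were lower on it and 43 higher. A choice on 1 infected array favours genes that are high on it by noise, so the other array looks lower. These 2 choices thus shift the counts in opposite directions and are no measure of the share that depends on MyD88.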

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

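Except for the comparison of dim and bright probe sets within a gene and the scaling test of the interferon genes, the tests in this part were chosen after their results were seen.

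Probe sets that carry no single gene name here were left out of the comparisons, and some of them differed with infection. With the array's control probe sets left out, 10092 such probe sets remained. Of these, 79 were at least 4-fold higher and 136 at least 4-fold lower in infected than uninfected wild type. On the MyD88-/- array, 45 of the higher ones were at least 2-fold lower than in infected wild type. The largest was a probe set with signals of 43.0, 4944 and 785 on the uninfected, infected wild-type and infected MyD88-/- arrays.

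The uninfected array carried a female pattern of Xist and Y-linked genes and both infected arrays a male one. An exchange of the wild-type arrays is argued against by the cytokine genes, whose median log2 difference of 4.73 was in the direction of the labels. Sex as the only cause of higher cytokine and interferon-stimulated genes is argued against too, because these fixed lists differed between the infected arrays, both with the male pattern, by medians of -2.31 and -3.21 relative to all genes; an effect of genotype on genes that differ by sex was not tested. For the 409 genes higher on both infected arrays, infection, sex and time in culture cannot be told apart. No uninfected male array was analysed here, and the labels do not say how long the uninfected cells stayed in culture. X-linked genes had a median of -0.31 with infection in wild type against -0.27 for all genes.

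More genes were lower than higher in infected wild type. A wrong factor for a whole array would shift all genes alike, whereas the median difference ranged by 0.71 over 5 bins of mean signal, from -0.58 to 0.13; yet equal medians, itself 1 factor per array, gave 1508 higher and 1338 lower, so a wrong factor stays open as a part. An array response that depends on signal may account for part of it: within 1562 genes with 2 or more probe sets at least 4-fold apart in signal and above the floor on all 3 arrays, the median gap of the dimmer minus the brighter probe set was -0.24 (95% of resampled medians from -0.29 to -0.20), and between genes of like signals the gap was -0.49. Scaling to the hybridization controls, which were 0.16 higher on the infected array, made the excess larger, with 770 higher and 2977 lower, and quantile normalization made it smaller, with 1247 and 1471. How much of the excess is infection, sex or time in culture, and how much is the array, stays open without a replicate.

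The interferon-stimulated list had a lower median on the array labelled MyD88-/- than in uninfected wild type. Of its 41 members 12 were at least 2-fold lower, 2 higher and 27 neither. Interferon-inducible GTPases, a separate list, lay at only -0.11 relative to all genes. Irf3 was lower on all 4 probe sets, while Bcl2l12, the gene next to it, differed by -0.41 and 0.50 from infected and by -1.78 and -1.11 from uninfected wild type on its probe sets. Signal near background stays open: the 28 members at least 4 times above the floor on both arrays compared had a median of -0.24 relative to all genes, a filter that removes lower members, and the 38 members with such a mean over 3 arrays, a form set after that value was seen, had -0.46, but these can pass through infected wild type alone. Under quantile normalization and equal medians the interferon-stimulated list stayed at or below -0.38, past the limit fixed beforehand as arguing against the deposited scaling. Resampling members, a term that limit did not hold, moved the median by 0.44, so the scaling was still counted as open. That term measures the spread over genes and not the scaling. Sex or other differences of the uninfected animals cannot be told apart from a lower resting level without MyD88 for the list's median of -0.68. Loss of the Irf3 transcript, by a mutation in these animals or by a sample of another genotype, is a candidate explanation. The least difference of an Irf3 probe set from either wild-type array was -1.28 with its lower side at the floor, so a bound. An effect of absent interferon on Irf3 is not ruled out. Ly6e and Ifi27l2a, which interferon induces, were near level in wild type (5427 and 2550 infected against 6079 and 2648 uninfected) and lower on this array (1709 and 605). Both were chosen after values were seen. In the fixed list, 40 of 41 interferon-stimulated genes were instead at least 2-fold higher with infection of wild type. Irf3 itself was level there only on its brightest probe set (692 uninfected, 711 infected). Its other probe sets were lower after infection, the most from 546 to 290.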

How the results depend on the processing

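The hybridization control scaling and the set without X and Y genes were chosen after the data were seen, the other settings before. No paired analysis was possible because every group had 1 array. Signal over background limits weak genes, whose folds are lower bounds. Of the list medians recomputed, 869 stayed alike, 16 moved and 2 turned sign. Of list percentiles 13 moved and 86 did not, and of the log2 differences of named genes 139 moved, 5 turned sign and 728 did neither; the cause was not tested. Over all settings interferon-stimulated genes lay between 2.46 and 2.61 relative to all genes with infection of wild type, between -3.22 and -3.10 in MyD88-/- against infected wild type and between -0.56 and -0.38 against uninfected wild type. Cytokine genes lay between 4.28 and 5.00, -2.45 and -2.08, and 1.67 and 1.85.

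Threshold: in infected against uninfected wild type 314 genes were higher and 369 lower at 4-fold, 1705 and 4300 at 1.5-fold. In MyD88-/- against infected wild type these were 25 and 166, and 2396 and 1104. In MyD88-/- against uninfected wild type they were 99 and 103, and 1229 and 2646. The split had 162 genes at 4-fold, 43 lower in MyD88-/- and 119 between, and 1345, 494 and 780 at 1.5-fold. Chosen on 1 infected array, 406 (wild type) or 83 (MyD88-/-) were lower, counts that such a choice itself shifts in opposite directions.

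Scaling: quantile normalization gave 1471 lower with infection of wild type and 382 higher in MyD88-/- against infected wild type. Equal medians gave 1508 higher and 1338 lower, and 363 higher, and an oxidative phosphorylation median of 0.0127. Hybridization controls gave 1141 higher in MyD88-/- against infected wild type, a doubled floor 459. Adding 16 to signals gave 1118 higher and 911 lower there, and 897 higher against uninfected wild type.

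Probe sets: macrophage identity was 0.0154 without less specific ones. Another probe set turned Ighm (0.12) and Ptx3 (0.57) in MyD88-/- against infected wild type, Slc39a14 (-0.51) against uninfected, and Ddit3 (-0.17) and Wipi1 (0.63) with infection of wild type.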

Other observations

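The test of held-out amino acid response genes and the check of genes near Myd88 were fixed before their values were seen; the amino acid response genes that prompted the former were chosen afterwards.

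A group of genes, most of them outside the fixed lists, was higher on both infected arrays. Chac1, a glutathione-degrading enzyme, had signals of 71.3, 1532 and 1489 on the uninfected, infected wild-type and infected MyD88-/- arrays. Asns, which makes asparagine, Phgdh, the entry enzyme of serine synthesis, and Mthfd2, a mitochondrial folate enzyme, were higher by log2 differences of 3.80, 3.39 and 3.23 in infected wild type and 3.62, 3.53 and 3.13 in infected MyD88-/-. Trib3 and Ddit3, members of the unfolded protein response list, were higher by 2.55 and 1.37 in infected wild type and 3.17 and 2.05 in infected MyD88-/-, but the other probe set of Ddit3 gave -0.17 and 0.36.

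These genes are known targets of ATF4, the transcription factor of amino acid shortage, and a candidate explanation is an ATF4 response present on both infected arrays. To test it, 35 other ATF4 targets were listed before their values were examined, and 34 were measured. Their median log2 difference from the uninfected array was 1.54 in infected wild type, with 22 at least 2-fold higher and 0 lower, and 1.33 in infected MyD88-/-, with 23 higher and 0 lower. Both medians were above all matched random lists, the 100th percentile, and the infected arrays differed by a median of -0.10 with 0 members 2-fold apart. That median lay below all but 63 of 10000 matched random lists, and all genes had 0.14, so the group was slightly lower in MyD88-/- than in infected wild type. Among the members, Sesn2, Slc7a1, Slc1a4 and Slc38a2, a stress sensor and 3 amino acid transporters, had differences of 2.61, 2.47, 2.46 and 2.22 in wild type. Bacterial growth in the medium, cell handling, time in culture and the sex difference of the uninfected array were not separated from infection of cells. The hypothesis thus covers the state of both infected samples and not its source.

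Interferon gamma transcript was above the floor on 1 array. Ifng was at 1048 in infected wild type and at 3.29 and 2.84 on the other arrays. Lymphocyte genes were mixed on that array, with Klrd1 at 41.0 and Cd3d at 32.3 below the floor. Gzmb, Klrk1 and Xcl1 were, like Ifng, above the floor on that array alone, at 108, 145 and 98.6. Prf1 and Cd247 were above it on every array and lowest on that one. Their signals were 718, 575 and 734, and 1228, 768 and 1015, on the uninfected, infected wild-type and infected MyD88-/- arrays.

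Knockouts made in cells of another strain can carry flanking alleles, so the genes around Myd88 on chromosome 9 were compared between the infected arrays. The 40 measured neighbours had a median absolute log2 difference of 0.39, at percentile 67.4 of matched random lists, with 4 genes higher and 1 lower at 2-fold. Of all measured genes 5.7% were higher and 4.5% lower at 2-fold. With 10 or 50 neighbours on each side the median was 0.41 and 0.37. The hypothesis of a differing strain background near Myd88 thus found no support. A median over these genes hardly moves when a few of them differ, so the check does not argue against flanking alleles either.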
